A study of Rattus norvegicus with 5 samples.

How the data were processed

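Rat genomic DNA was studied by immunoprecipitation with an antibody against N6-methyladenine (6mA), followed by sequencing. The DNA was sonicated, adapters were ligated, and the fragments were denatured and enriched with the antibody, then eluted with 6mA monophosphate. Neural stem cells (NSCs, the SCR022 line of adult rat hippocampal stem cells), Neurons and Astrocytes gave 1 immunoprecipitated library each. Input libraries, made from the same kind of DNA without enrichment, were part of the samples for NSCs and for Neurons. The 5 libraries therefore hold 1 library per cell type and kind, and no replicate. No test between cell types was possible, and no p was computed here. The mapping summary also lists 1 astrocyte input without a sample of its own, and its numbers were not used here.

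Reads were aligned with BWA, as the submitters' processing notes state without a version. The genome build, the annotation source, the filters and the version of the peak caller are not given in the sources used here. The deposited mapping summary gives reads as counts per library, and mapping rates as a percent of the library's reads. Uniquely mapped reads labelled as in the same chromosome are deposited as another read number per library. The authors' peak lists compare each immunoprecipitated library with its input, in the naming style of MACS, the astrocyte list included. Their score is deposited as 10 times the −log10 p, with a minimum of 50 in every list (p of 1e-05). The authors' fold enrichment is a ratio of the library to its input or, in the comparison tables, of 1 immunoprecipitated library to another. The deposited GO and KEGG tables give gene counts and an adjusted p-value per term, as the authors computed them, with genes counted as hit when any gene class held a peak. Each of the 3 cell type pairs has a pair of deposited comparison tables, 1 for each direction, which makes 6 comparison lists. Regions higher in the first library of a comparison had the coordinates of that library's own peaks wherever they overlapped one. Regions higher in the second library were called separately, and 31.9% to 37.1% of them were identical to a peak of that library, so both directions differ in how they were made.

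Peaks were read as deposited, and 6 blank lines were skipped. Scores and folds were used to describe and rank within a list. The stricter score and the stricter fold were each a single cut, taken over all lists of a kind and applied to each of them. Folds printed side by side for the cell types come from separate lists and were not compared. Peaks in separate lists were called shared when they overlapped by at least 1 bp. The observed share stands beside the mean of 100 seeded shuffles that kept each peak's length and chromosome. Annotation classes are those of the deposited files: promoter, upstream and downstream 2 kb, exon, intron, gene body, CpG island and CpG island shore. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only, since reads and neighbouring peaks are not independent molecules. Density per chromosome used the largest region end on each of 22 chromosomes as its length. Overlap of comparison lists that share a library was counted over 220998 merged peak regions. It stands beside the number for independent lists and beside 100 simulations in which 3 unrelated libraries, 1 of them shared by both comparisons, were compared.

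Before the data were examined, 22 gene lists with 488 different genes were fixed. They cover the 2 genes of the series title, adenine methylation enzymes, redox enzymes, stem cell, neuronal fate, neuronal structure, synaptic, receptor and channel genes, markers of Astrocytes, oligodendrocytes, microglia and vessels, Notch, Wnt and BMP signalling, axon guidance, cell cycle, respiration, ribosome and liver genes. Long genes hold more peaks, so each list was set beside 10000 seeded random lists of as many protein-coding genes, matched on 10 length bins. Gene lengths came from the RefSeq annotation of the GRCr8 assembly. Its coordinates were not used, since the build of the files is not given. Of 488 list genes, 487 were matched by symbol, and the random lists were drawn from 20943 genes. Of 21230 symbols with a peak, 14873 (70.1%) were matched; without placeholder names, 12206 of 12309 (99.2%) were. Neuron peaks inside 885 genes spanned lengths that followed the reference length across genes, with a Spearman rho of 0.805; genes are not independent replicates.

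Genes were named by a rule fixed before the data were examined. It took the list members with the largest authors' fold, 10 genes with a placed and named region of the largest fold per list, both genes of the series title everywhere, and the 10 genes of at least 20 kb with the most regions per 100 kb among genes with at least 5 regions. For the last part, gene length was the larger of the reference length and the extent of the gene's own peaks. That definition was chosen after the values were seen, because a few genes were far longer in the files than in the reference. Some genes that the rule takes are left out of the text.

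Alternatives fixed beforehand were a stricter score (at least 87.44), a fold of at least 9.53 in the comparison lists, 50% reciprocal overlap, equal list sizes, autosomes only, covered length in place of number, gene bodies only, random lists not matched on length, and a p of 0.001 for terms. Finer length matching with 50 bins, and the stricter score in 1 list against all peaks of the others, were added after seeing the data. The sequence content of peaks was not analysed here, because no genome of the files' build was at hand. Off-target binding of the antibody, for example to short tandem repeats, was therefore not checked. The overlap and list procedures were tested on simulated data. Each of 20000 simulated regions was put, with equal chance, on an NSC peak or on a chromosome without peaks, where it could not overlap. All were classed correctly. Of 200 random lists of 25 genes with no effect, 5.5% fell outside the central 95%, and with 30 percentage points more members hit, 94.5% of lists lay above it. These lists were drawn from all genes. Hits were simulated at a fixed rate within each of the 10 length bins, taken from Neuron peaks. The test therefore does not check effects of length within a bin, nor the comparison lists. Lists of long genes, where random lists already had nearly all members hit, cannot gain 30 points, so the test does not cover them in the peak lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.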

Results

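DNA regions enriched by an antibody against 6mA were mapped in rat NSCs, Neurons and Astrocytes. There was 1 immunoprecipitated library per cell type, with inputs for NSCs and Neurons. Whether an enriched region holds 6mA was not checked by another measure here. The series title names the methyltransferase N6amt1 and the gene Txnrd3, a thioredoxin reductase, in hippocampal neurogenesis. The immunoprecipitated libraries held 15760246 reads in NSCs, 16095308 in Neurons and 15767015 in Astrocytes, of which 13785430, 13930646 and 13866225 mapped uniquely. The inputs held 27936774 reads in NSCs and 22329441 in Neurons, of which 27729210 and 22212721 mapped uniquely. Unmapped reads made up 10.3%, 10.2% and 9.59% of the NSC, Neuron and Astrocyte libraries, and 0.259% and 0.189% of the NSC and Neuron inputs. Each cell type had 1 library, so no difference below could be held against a spread between replicates. Peak scores and folds are the authors' own, and positions are as the files give them on a build not given in the sources used here.

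The first question was where peaks of the 6mA antibody lay in each cell type. Neurons had 137579 peaks, NSCs 121816 and Astrocytes 116091, covering 69.8, 63.8 and 58.1 Mb. Most peaks lay outside any annotated gene class: 62.2% in NSCs, 61.4% in Neurons and 61.2% in Astrocytes. Gene bodies held 34.2% of NSC peaks (95% interval 33.9 to 34.4), 34.7% of Neuron peaks (34.46 to 34.96) and 34.99% of Astrocyte peaks (34.7 to 35.3), nearly all of them in introns. Promoters held 2.97%, 3.20% and 3.02%, exons 2.78%, 3.05% and 2.89%, and CpG islands 0.149%, 0.210% and 0.164% of NSC, Neuron and Astrocyte peaks. The share of the genome in each class was not established here, so these shares cannot show enrichment or depletion. The median peak was 467 bp wide in NSCs, 456 bp in Neurons and 447 bp in Astrocytes.

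Among placed NSC peaks with a gene name, the largest folds lay in introns of Rreb1, a zinc finger transcription factor (fold 227, chromosome 17, 27564692 to 27565197), Chd9, a chromatin remodeller (205, chromosome 19, 17503602 to 17504173), and Dab1, an adaptor of the Reelin pathway in neuronal migration (187, chromosome 5, 124192060 to 124192840). Tnfaip8l2, Fgd6, Zfp277, Soga3, Cast, Fryl and Irgc followed with folds from 176 to 158, and the Irgc peak was the one in a promoter. Among placed Neuron peaks with a gene name, the largest folds lay in introns of Yeats2, a chromatin reader (237, chromosome 11, 84503612 to 84504081), Kcnip2, a potassium channel partner (235, chromosome 1, 265556935 to 265557911), and Dym (210, chromosome 18, 71245995 to 71246503). Spink4, Adamts19, Antxr1, Hpse2, Prune2, Pde3a and Stxbp5, which binds syntaxin, completed the Neuron set with folds from 205 to 187. Among placed Astrocyte peaks with a gene name, Fam129a led (278, chromosome 13, 69089064 to 69089678), before Pde3a, a cyclic nucleotide phosphodiesterase (275, chromosome 4, 175629643 to 175630319), and Map2k1, a kinase of the ERK cascade (264, chromosome 8, 69406781 to 69407587). Dym, Yeats2, Adamts19, Asz1, Park2, Prune2 and Hpse2 followed in Astrocytes with folds from 252 to 202. Yeats2, Dym, Adamts19, Prune2, Pde3a and Hpse2 were thus among the 10 genes with the largest folds in both Neurons and Astrocytes.

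Relative to gene length, Zim1 held the most peaks in NSCs and in Neurons, with 6 peaks and 27.7 per 100 kb in each. Glipr1l1, Cdca8, a protein of the chromosomal passenger complex, Adgrf4, Zfp92, Tmem130, Krt71, Myl10, Cybrd1 and Cacng4 followed in NSCs, from 25.9 down to 17.7 per 100 kb. In Neurons, Calr3, Mall, Tmem130, Cybrd1, Hif3a, Otulinl, Vom2r26, Sarm1, an axon degeneration enzyme, and Muc13 followed, from 26.2 down to 20.9 per 100 kb. In Astrocytes, Tmem130 had 7 peaks and 27.1 per 100 kb, followed by Calr3, Fam163b, Dao, Sarm1, Trib2, Actg2, Arhgap40, Prdm1 and Nr1h5, from 22.5 down to 19.0 per 100 kb.

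Txnrd3, on chromosome 4, held 5 peaks in Neurons, 3 in Astrocytes and 2 in NSCs. Neurons had a peak in its promoter, in a CpG island shore (121611399 to 121611828, fold 13.3, score 105), which neither NSCs nor Astrocytes had. In the comparison lists the promoter was higher in Neurons and in Astrocytes than in NSCs. It was not listed as different between Neurons and Astrocytes. The other Neuron peaks lay at 121620301 to 121620719 (exon and intron, fold 12.1), and in introns at 121639204 to 121639585 (13.0), 121641828 to 121642324 (11.6) and 121645578 to 121646287 (8.62). The NSC peaks were intronic, at 121642950 to 121643355 (fold 9.72) and 121645855 to 121646151 (11.2). The Astrocyte peaks were intronic too, at 121620375 to 121620798 (fold 9.62), 121643034 to 121643354 (10.4) and 121645681 to 121646200 (9.97). Most of these scores were low: at the stricter score, Neurons kept 2 of the Txnrd3 peaks, Astrocytes 1 and NSCs 0. N6amt1 held no region in any list. The series title names both genes, and how the study chose them is not given in the sources used here.

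**Figure D1:**
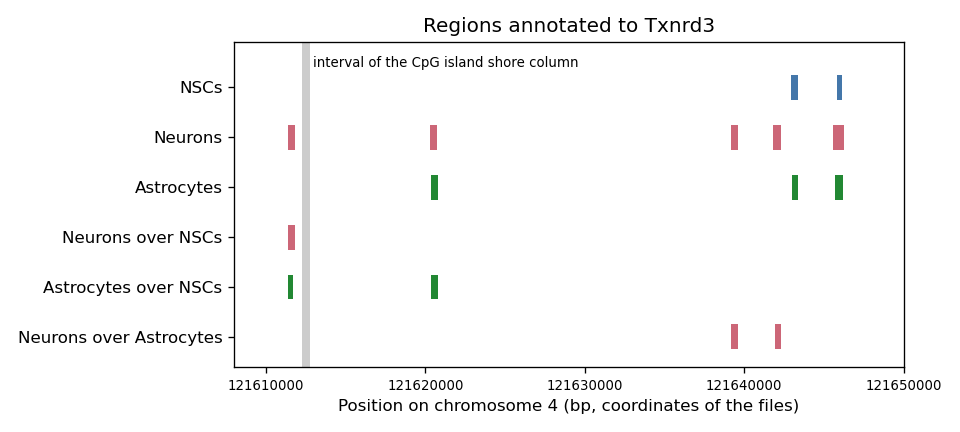
Regions annotated to Txnrd3 in the 3 peak lists and in the 3 comparison lists that held any, drawn to scale along chromosome 4 in bp. Colours mark the cell type in which a region was called or higher, and the grey bar is the interval the files give in their CpG island shore column. The promoter region at the left was a peak in Neurons and was higher in Neurons and in Astrocytes than in NSCs.

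Peaks in the fixed gene lists followed gene length. In NSCs, a peak was found in 10.8% of the genes of the shortest length decile (median 0.939 kb) and in 91.7% of those of the longest (median 197 kb). Receptor, channel and adhesion genes, which are long, held peaks almost throughout. All 20 glutamate receptor genes had a peak in NSCs and 19 in Neurons and in Astrocytes, led by Grid1 (fold 102 in NSCs, 170 in Neurons and 131 in Astrocytes). Of 23 voltage-gated channel genes, 22 had a peak in each cell type, among them the calcium channel subunits Cacna2d3 (102 in NSCs) and Cacna2d1 (152 in Neurons and 149 in Astrocytes). Of 30 synaptic adhesion and scaffold genes, 28 had a peak in NSCs and Neurons and 27 in Astrocytes, with Nrxn3 at 139 in Neurons and Dlgap1 at 167 in Astrocytes. For GABA and glycine signalling, 19 of 20 genes had a peak in each cell type. Axon guidance genes had a peak in 32 of 35 cases in NSCs and 33 in Neurons and in Astrocytes, with Dcc, a netrin receptor, at 74.0, 66.4 and 70.0.

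Stem cell genes had a peak in 11 of 22 cases in NSCs, 11 in Neurons and 12 in Astrocytes, with Lpar1 at 59.6, 93.6 and 65.6. Neuronal fate factors had one in 18, 20 and 19 of 29 cases, led by the transcription factor Zbtb20 (126, 182 and 112), and neuronal structure genes in 15, 16 and 14 of 21. Astrocyte markers had one in 13 of 25 cases in NSCs, 18 in Neurons and 13 in Astrocytes, with the transcription factor Nfia at 88.9, 134 and 78.3. Oligodendrocyte genes had 9, 10 and 10 of 15, microglia genes 7, 8 and 7 of 14, and vessel genes 8 of 11 in each cell type. Notch genes had 13, 15 and 14 of 21, Wnt genes 16, 17 and 16 of 27, and BMP and TGF-beta genes 20, 21 and 19 of 28. Cell cycle genes had 11, 13 and 14 of 34, respiration genes 12, 9 and 11 of 32, and liver genes 10, 12 and 11 of 21. Redox genes had 9, 11 and 11 of 24, with Sod1 at 35.9, 51.9 and 33.1. Adenine methylation enzymes had 5, 6 and 4 of 12, led by the RNA demethylase Fto (55.1, 39.1 and 60.7).

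Against random lists matched on gene length, 0 of the 66 pairs of gene list and peak list lay above the central 95% and 1 lay below it. GABA and glycine genes, with 19 of 20, equalled their upper random limit in each cell type. They lay at percentiles 97.33, 95.3 and 97.46 in NSCs, Neurons and Astrocytes. The upper random limit was the whole list for the 2 genes of the series title, the 20 glutamate receptor genes and the 23 channel genes, so these could not exceed it. The pair below was ribosomal protein genes in Neurons, where 1 of 31 genes had a peak and random lists had 2 to 10 in their central 95%. In NSCs and in Astrocytes 3 of the 31 had a peak. With gene bodies only, the Neuron count lay at percentile 3.46, and at the stricter score at 10.4. At the stricter score 8 pairs lay above the central 95%, and without matching on length 24 did.

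The next question was how far the peaks were shared. Of NSC peaks, 58.1% overlapped a Neuron peak and 53.4% an Astrocyte peak, where shuffled peaks gave 5.11% and 4.30%. Of Neuron peaks, 51.5% overlapped an NSC peak and 50.9% an Astrocyte peak, where shuffles gave 4.52% and 4.24%. Of Astrocyte peaks, 56.1% overlapped an NSC peak and 60.4% a Neuron peak, where shuffles gave 4.51% and 5.02%. Peaks found in both other cell types made up 43.6% in NSCs, 38.6% in Neurons and 45.8% in Astrocytes. With the 58045 highest-scoring peaks of each list, which made sizes equal and scores stricter at once, they made up 54.2%, 54.1% and 54.3%. At the stricter score in all lists they made up 54.4%, 47.2% and 57.1%. With the stricter score in 1 list against all peaks of the others, chosen after seeing the data, they made up 68.7%, 62.8% and 71.8%. Peaks found in neither made up 32.1% in NSCs, 36.1% in Neurons and 29.2% in Astrocytes. This share fell with the score, from 62.4% in the lowest decile of NSC scores to 0.107% in the highest, from 66.6% to 0.0291% in Neurons and from 59.8% to 0.00861% in Astrocytes. With no repeated library of a cell type, the overlap of repeated libraries is unknown.

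**Figure D2:**
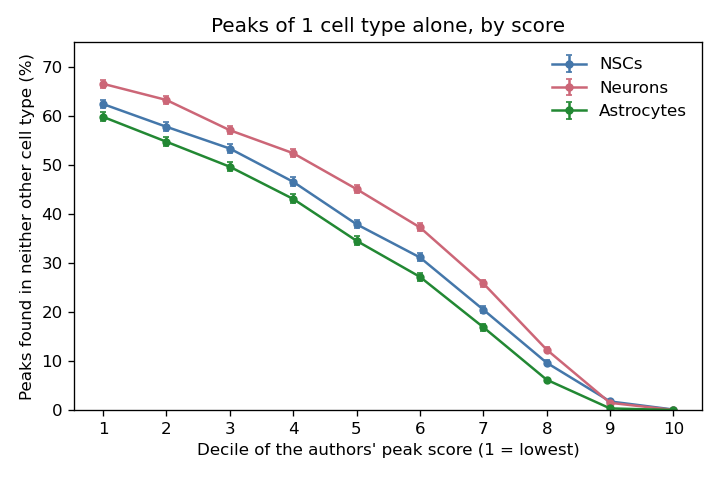
Percent of peaks found in neither other cell type (vertical axis) by decile of the authors' score (horizontal axis), with exact 95% intervals that cover counting error only. The 3 lines fall from between 59.8% and 66.6% to 0.107% or less.

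Along the chromosomes, chromosome 12 was the densest autosome in NSCs (57.3 peaks per Mb), Neurons (68.5) and Astrocytes (57.1). Chromosome 14 was the sparsest in each, with 27.4, 30.5 and 25.2 peaks per Mb, where the median autosome had 46.5, 52.5 and 44.3. The X chromosome had 0.708, 0.687 and 0.665 times the density of the autosomes.

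**Figure D3:**
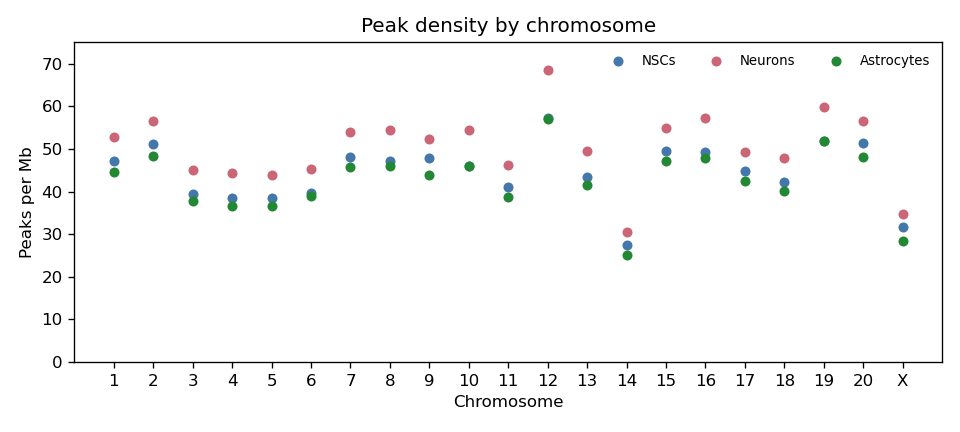
Peaks per Mb (vertical axis) on each autosome and the X chromosome (horizontal axis), with 1 point per cell type. Chromosome 12 is highest and chromosome 14 is lowest, at 27.4, 30.5 and 25.2 peaks per Mb in NSCs, Neurons and Astrocytes.

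Neurons were compared with NSCs to find enriched regions that differ between the neuronal and the stem cell library. The authors' deposited table listed 32213 regions higher in Neurons and 27634 higher in NSCs, a ratio of 1.17. Gene bodies held 36.9% of the regions higher in Neurons (95% interval 36.4 to 37.4) and 35.6% of those higher in NSCs (35.1 to 36.2). CpG islands held 0.559% (0.480 to 0.646) and 0.380% (0.311 to 0.460). Of the regions higher in Neurons, 15.7% were not in a Neuron peak, and of those higher in NSCs, 25.7% were not in an NSC peak. The median width was 441 bp for the first and 406 bp for the second, which were called separately.

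Among placed regions with a gene name, the largest folds for Neurons over NSCs in the authors' deposited table included those in introns of Pappa2, a protease of insulin-like growth factor binding proteins (30.8, chromosome 13, 76472340 to 76472743), Dpp10, a potassium channel partner (29.6), and Vdr, the vitamin D receptor (28.01). Pxdn, Atp6v1h, a proton pump subunit, Dner, a neuronal Notch ligand, Col22a1, Med17 (in an intron shared with Hephl1) and Phlpp1 followed at 27.2 to 27.1 in the authors' deposited table. Ppl had the densest regions (5, or 10.95 per 100 kb), then Slc6a17, a vesicular amino acid transporter (10.4), Jph2, Otoa, Fam13a, Mrtfa, Mipep, Spetex2c, Cit and Slc6a11, a GABA transporter (4.34). For NSCs over Neurons, the largest folds of such named regions in the authors' deposited table lay in introns of Dbr1, the RNA lariat debranching enzyme (33.4, chromosome 8, 107827247 to 107827469), Tbc1d4 (29.7), Map2k3, a kinase of the p38 pathway (29.6), and Ccdc82 (28.2). Zfp385d, Lrch2, Commd10, Ak3, Nell1 and Palld followed at 28.1 to 22.3 in the authors' deposited table. Dpy19l2 had the densest regions (8, or 6.71 per 100 kb), and those that followed included Sptbn4 (5.71), Clip4, Trip4, Pth2r, Ubash3b, Zfp608, Slmap and the AMPA receptor gene Gria2 (4.16).

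Txnrd3 had 1 region higher in Neurons, its promoter peak (121611399 to 121611828, fold 12.5 and score 92.5 in the authors' deposited table), and 0 higher in NSCs. Axon guidance genes had a region higher in Neurons in 31 of 35 cases, where random lists had 19 to 29, and a region higher in NSCs in 24 cases, within the random range. Epha7, an ephrin receptor (fold 19.7), Sema5a (18.7) and Unc5d, a netrin receptor (18.5), led them in the authors' deposited table. Voltage-gated channel genes had a region higher in Neurons in 21 of 23 cases (random 12 to 20), led by the sodium channel gene Scn1a (23.8) and Kcnma1 (20.97) in the authors' deposited table. They had one higher in NSCs in 18 cases (random 11 to 19). Astrocyte marker genes had a region higher in Neurons in 14 of 25 cases (random 5 to 13), among them Gpc5 (19.7) and Glul, glutamine synthetase (14.8), in the authors' deposited table. They had one higher in NSCs in 9 cases (random 4 to 12). Synaptic adhesion genes had a region higher in NSCs in 24 of 30 cases (random 13 to 23), led by Lrrtm4 (20.97) and Nlgn1 (19.7) in the authors' deposited table, and a region higher in Neurons in 24 cases too (random 16 to 25). Microglia genes had 7 regions higher in Neurons, in 5 of 14 genes, and 0 higher in NSCs, with Ptprc at 11.1 in the authors' deposited table. Both member counts lay within the random range (0 to 6 for Neurons and 0 to 5 for NSCs). All named genes together had 54.9% of their regions higher in Neurons, outside the 59.0% to 100% interval of the microglia genes. The intervals of axon guidance genes (59.2%, interval 52.3% to 65.8%) and channel genes (60.9%, 52.9% to 68.5%) held 54.9%. So did those of astrocyte marker genes (57.1%, 44.0% to 69.5%) and synaptic adhesion genes (52.4%, 46.9% to 57.9%).

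The other lists lay within the random range in both directions. Counts of members with a region higher in Neurons and in NSCs were 17 and 17 of 20 for glutamate receptors, 13 and 13 of 20 for GABA and glycine signalling, 14 and 12 of 29 for neuronal fate factors, 9 and 6 of 21 for neuronal structure and 9 and 6 of 22 for stem cell genes. They were 8 and 5 of 21 for Notch, 9 and 12 of 27 for Wnt, 10 and 9 of 28 for BMP and TGF-beta, 5 and 6 of 34 for cell cycle, 6 and 5 of 24 for redox, and 3 and 5 of 12 for methylation enzymes. Oligodendrocyte genes had 3 and 3 of 15, vessel genes 5 and 5 of 11, respiration genes 3 and 5 of 32, ribosomal protein genes 1 and 1 of 31 and liver genes 4 and 2 of 21. The astrocyte count fell to percentile 91.0 with gene bodies only. With 50 length bins, the channel genes lay at percentile 97.1 and the adhesion genes at 93.2.

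**Figure D4:**
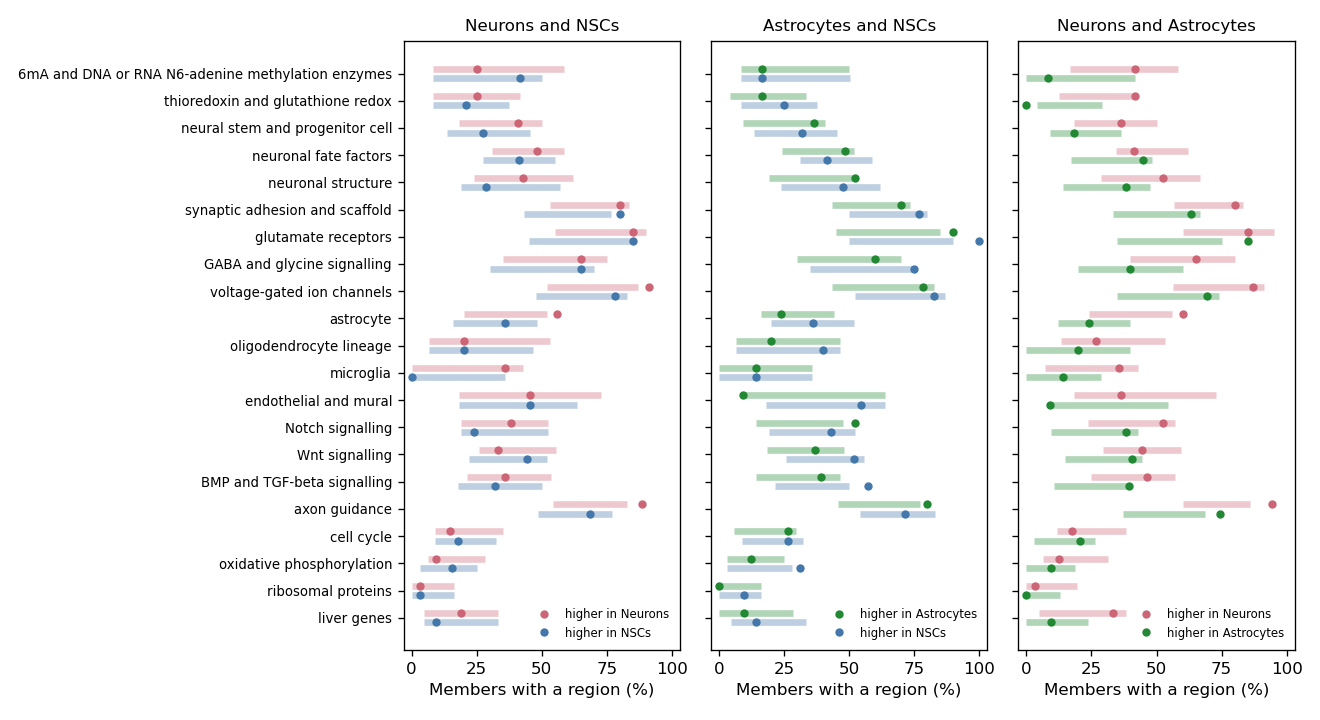
Percent of each fixed gene list with a region higher in a cell type (points, horizontal axis), with the central 95% of length-matched random lists (bars), in the 3 comparisons. Axon guidance lies beyond its bar for Neurons over NSCs, with 31 of 35 genes.

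Astrocytes were compared with NSCs in the same way. The authors' deposited table listed 21671 regions higher in Astrocytes and 32105 higher in NSCs, a ratio of 0.675. Gene bodies held 37.7% of the regions higher in Astrocytes (95% interval 37.1 to 38.4) and 35.2% of those higher in NSCs (34.7 to 35.7), and exons held 4.96% (4.68 to 5.26) and 4.02% (3.81 to 4.24). Of the regions higher in Astrocytes, 19.8% were not in an Astrocyte peak, and of those higher in NSCs, 23.4% were not in an NSC peak. The median width was 415 bp for the first and 381 bp for the second.

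For Astrocytes over NSCs, the largest folds among placed regions with a gene name in the authors' deposited table lay in introns of Rab43 (31.9, chromosome 4, 119709513 to 119710074), Ankrd55 (31.8), Ash1l, a histone methyltransferase (26.6), Ube4b (25.2) and Syne2, which links the nucleus to the cytoskeleton (25.1). Poln, the olfactory receptor gene Olr29 in its promoter, Slco5a1, Erp27 and Scaper followed at 24.8 to 23.9 in the authors' deposited table. The densest regions were those of Prtfdc1 (7, or 6.65 per 100 kb) and Slc1a1, a glutamate transporter (6.24), then Spetex2c, Frk, Klhl2, Shc3, Mipep, Tox2, Synpo2 and Slc22a23 (3.62). For NSCs over Astrocytes, Dbr1 again led the named regions in the authors' deposited table (36.2, chromosome 8, 107827257 to 107827459), before Man1a2, a Golgi mannosidase (31.9), Lnpep (30.6), Ryk, a Wnt receptor (30.6), and Sparcl1, an astrocyte-secreted matrix protein (29.2). Tspan13, Adamdec1, Abcb11, the AMPA receptor gene Gria4 and Trappc9 followed at 29.2 to 25.8 in the authors' deposited table. Zfp182 had the densest regions (5, or 6.76 per 100 kb), then Sult2a6, the transcription factor gene Pax2 (5.48), Tsga10, Tbc1d9, Cast, Smad3, a TGF-beta signal transducer, Grhl2, Rnf130 and Dennd4a (4.41).

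Txnrd3 had 2 regions higher in Astrocytes and 0 higher in NSCs. In the authors' deposited table they were its promoter (121611357 to 121611720, fold 11.96, score 51.8), where Astrocytes had no peak of their own, and an intron (121620375 to 121620798, fold 14.6, score 74.6). All 20 glutamate receptor genes had a region higher in NSCs (random 10 to 18), led by Gria4 (27.9), Grm8 (19.9) and Grik2 (18.6) in the authors' deposited table. Of these 20, 18 also had a region higher in Astrocytes (random 9 to 17), led by Grm8 (22.6) in the authors' deposited table. Axon guidance genes had a region higher in Astrocytes in 28 of 35 cases (random 16 to 27), and one higher in NSCs in 25 cases (random 19 to 29). The Slit receptors Robo2 (17.3) and Robo1 (16.6) led those higher in Astrocytes in the authors' deposited table. Notch genes had a region higher in Astrocytes in 11 of 21 cases (random 3 to 10), and one higher in NSCs in 9 cases (random 4 to 11). The coactivator Maml3 (14.6) and the protease Adam10 (14.6) were at the top of those higher in Astrocytes in the authors' deposited table. BMP and TGF-beta genes had a region higher in NSCs in 16 of 28 cases (random 6 to 14), led by Smad3 (18.5) and Acvr1 (16.1) in the authors' deposited table. They had one higher in Astrocytes in 11 cases (random 4 to 13). Respiration genes had a region higher in NSCs in 10 of 32 cases (random 1 to 9), led by the complex I genes Ndufs4 (14.2) and Ndufa9 (13.4) in the authors' deposited table. They had one higher in Astrocytes in 4 cases (random 1 to 8). GABA and glycine genes lay at percentile 97.7 for NSCs, with 15 of 20 (random 7 to 15), led by Gabra2 (23.9) in the authors' deposited table. For Astrocytes they had 12 of 20 (random 6 to 14). Vessel genes had a region higher in Astrocytes in 1 of 11 cases (Rgs5, random 1 to 7, percentile 2.10), and one higher in NSCs in 6 cases (random 2 to 7). They had 1 region higher in Astrocytes and 11 higher in NSCs, or 8.33% (interval 0.211% to 38.5%), where all named genes had 42.2%.

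The remaining lists lay within the random range. Members with a region higher in Astrocytes and in NSCs were 6 and 9 of 25 for astrocyte markers, 8 and 7 of 22 for stem cell genes, 14 and 12 of 29 for neuronal fate factors, 11 and 10 of 21 for neuronal structure, 21 and 23 of 30 for synaptic adhesion and 18 and 19 of 23 for channels. They were 10 and 14 of 27 for Wnt, 9 and 9 of 34 for cell cycle, 4 and 6 of 24 for redox, 2 and 2 of 12 for methylation enzymes, 3 and 6 of 15 for oligodendrocyte genes, 2 and 2 of 14 for microglia, 0 and 3 of 31 for ribosomal protein genes and 2 and 3 of 21 for liver genes. With 50 length bins, the glutamate receptor count for Astrocytes lay at percentile 97.3, the GABA count at 97.1 and the vessel count at 3.63. Without matching on length, the respiration count lay at percentile 76.7.

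Neurons were compared with Astrocytes as the pair of differentiated cell types. The authors' deposited table listed 39716 regions higher in Neurons and 16599 higher in Astrocytes, a ratio of 2.39. Gene bodies held 36.3% (95% interval 35.9 to 36.8) and 37.1% (36.4 to 37.9) of them, and CpG islands 0.519% and 0.506%. Of the regions higher in Neurons, 23.4% were not in a Neuron peak, and of those higher in Astrocytes, 21.9% were not in an Astrocyte peak. The median width was 381 bp for the first and 401 bp for the second.

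For Neurons over Astrocytes, the largest folds among placed regions with a gene name in the authors' deposited table lay in Dner, the Notch ligand (28.6, chromosome 9, 92289363 to 92289800), Clasp1, a microtubule-binding protein (27.3), Tfec (26.0), Ubap2 (26.0) and Cacna1e, a calcium channel subunit (26.0). Med17, Upf2, a factor of nonsense-mediated RNA decay, Wdr33, Cntnap2, a neurexin family member, and Cd1d1 followed at 25.9 to 23.5 in the authors' deposited table. The Dner region had the same coordinates as the one higher in Neurons than in NSCs. Kif2a, a microtubule-depolymerising kinesin, had the densest regions (5, or 7.91 per 100 kb), then Zc3h13, of the RNA methyltransferase complex (7.75), Otoa, B4galnt3, Flt3, Slc4a7, Cryl1, Ntn4, Ccdc6 and Insr, the insulin receptor (5.07). For Astrocytes over Neurons, Ptprm, a receptor phosphatase, led the named regions in the authors' deposited table (39.0, chromosome 9, 115470834 to 115471359), before Adamts9 in its promoter (27.3), the netrin receptor gene Unc5d (24.9) and Rbsn (24.7). Rab38, Cnksr2, Fndc3a, St6gal2, Klf12 and Bcl2l11, a promoter of apoptosis, followed at 24.7 to 22.6 in the authors' deposited table. Dpy19l2 (5 regions, 4.19 per 100 kb) and Lama4, a laminin chain (3.54), were densest, before Zbtb16, Galnt14, Tnni3k, Ext1, Ankrd44, Ntng1, Itgbl1 and Bank1 (1.85).

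Txnrd3 had 2 intronic regions higher in Neurons, at 121639204 to 121639585 (fold 8.01) and 121641923 to 121642314 (fold 9.81) in the authors' deposited table, and 0 higher in Astrocytes. Its promoter was listed in neither direction of this comparison. Redox genes had 16 regions higher in Neurons and 0 higher in Astrocytes, an interval of 79.4% to 100%, where all named genes had 70.2% higher in Neurons. The 2 Txnrd3 regions are among these 16, and regions of the same gene are not independent. It was 1 of 3 intervals among 66 that left out the value of all named genes. Regions higher in Neurons lay in 10 of the 24 redox genes (random 3 to 10), led by the glutathione synthesis genes Gclc (12.01), Gss (11.7) and Gclm (10.8) in the authors' deposited table, and regions higher in Astrocytes in 0 (random 1 to 7). Axon guidance genes had a region higher in Neurons in 33 of 35 cases (random 21 to 30), led by Ephb1 (22.1), Unc5d (20.9) and Dcc (20.8) in the authors' deposited table. They also had a region higher in Astrocytes in 26 cases (random 13 to 24), led by Unc5d (24.9), Dcc (18.2) and Robo1 (15.4) in the authors' deposited table. Glutamate receptor genes had a region higher in Astrocytes in 17 of 20 cases (random 7 to 15), led by Gria4 (16.9) and Grik2 (15.2) in the authors' deposited table, and one higher in Neurons in 17 cases (random 12 to 19). Astrocyte marker genes had a region higher in Neurons in 15 of 25 cases (random 6 to 14), led by Gpc5 (22.1) and Slc4a4, a bicarbonate transporter (15.6), in the authors' deposited table, and one higher in Astrocytes in 6 cases (random 3 to 10). By direction, 70.4% of the regions in astrocyte marker genes were higher in Neurons (interval 56.4% to 82.0%), near the 70.2% of all named genes. The shares for glutamate receptor and axon guidance genes, 71.7% and 68.0%, were near it too.

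Lists within the random range had these members with a region higher in Neurons and in Astrocytes: 24 and 19 of 30 for synaptic adhesion, 20 and 16 of 23 for channels, 13 and 8 of 20 for GABA and glycine signalling, 12 and 13 of 29 for neuronal fate factors, 11 and 8 of 21 for neuronal structure and 8 and 4 of 22 for stem cell genes. They were 11 and 8 of 21 for Notch, 12 and 11 of 27 for Wnt, 13 and 11 of 28 for BMP and TGF-beta, 6 and 7 of 34 for cell cycle, 5 and 1 of 12 for methylation enzymes and 4 and 3 of 15 for oligodendrocyte genes. Microglia genes had 5 and 2 of 14, vessel genes 4 and 1 of 11, respiration genes 4 and 3 of 32, ribosomal protein genes 1 and 0 of 31, and liver genes 7 and 2 of 21. The astrocyte marker count for Neurons lay at percentile 92.9 with gene bodies only, and the glutamate receptor count for Astrocytes at 96.6 with 50 length bins. Over the 3 comparisons, 15 of 132 pairs of gene list and region list lay above the central 95% of random lists and 2 below it by mid-rank percentile. By the printed ranges 14 lay above and 1 below, since the GABA count for NSCs over Astrocytes and the vessel count for Astrocytes over NSCs equalled their limits. With 50 length bins, 10 lay above and 1 below by mid-rank percentile. Of intervals on direction, 3 of 66 left out the value of all named genes. A central 95% range leaves some pairs outside by chance.

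**Figure D5:**
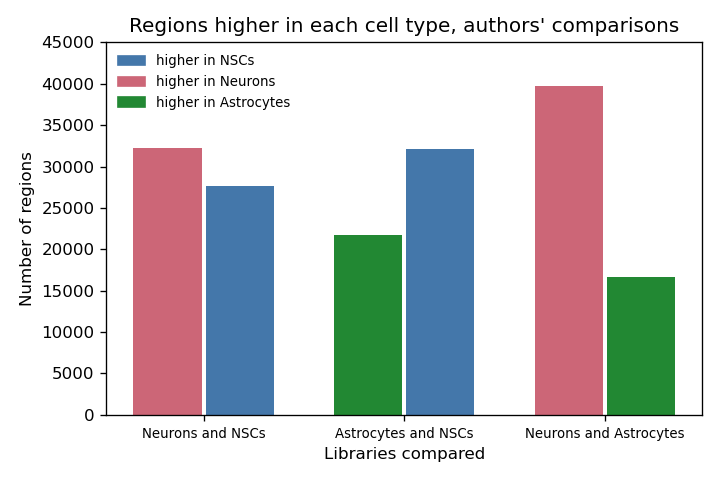
Number of regions higher in each cell type (vertical axis) in the authors' 3 comparisons (horizontal axis). Neurons have more regions than NSCs and than Astrocytes, with 39716 against 16599 in the last pair.

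Regions that differed in the same direction in both comparisons of a cell type were counted over 220998 merged peak regions. NSCs were higher than both other cell types in 10049 of them, where independent lists gave 2361 and simulated libraries with 1 in common gave 7480. Neurons were higher than both others in 11661 (independent 3824, simulated 10564), and Astrocytes in 5489 (1050 and 4210). NSCs were lower than both others in 4273 (2190 and 7052), Neurons in 1984 (1238 and 4705) and Astrocytes in 4726 (3495 and 9894). Each count of higher regions was thus above its simulated number, and each count of lower regions below it. The simulation drew symmetric random values for every region, whereas each merged region was chosen because at least 1 cell type had a peak there. The simulated numbers therefore cannot decide whether the overlap was more or less than a shared library gives.

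The authors tested genes with a peak for GO and KEGG terms in each cell type. At an adjusted p under 0.05, a cut applied here, the authors' deposited tables held 75 GO terms in NSCs, 58 in Neurons and 79 in Astrocytes, of which 55 were held in all 3. KEGG pathways numbered 67, 48 and 77, of which 43 were held in all 3. These counts pool terms above and below chance, such as 61 and 14 GO terms in NSCs. Olfactory transduction held fewer genes with a peak than the authors' deposited table gave by chance, at 0.407 times in NSCs, 0.410 in Neurons and 0.375 in Astrocytes. The ribosome pathway lay at 0.378, 0.410 and 0.395 times in the authors' deposited table. Focal adhesion lay above chance at 1.73, 1.59 and 1.69 times, axon guidance at 1.65, 1.57 and 1.69 times, and glutamatergic synapse at 1.80, 1.71 and 1.84 times in the authors' deposited table. The authors' chance values were a fixed share of each term's genes and were not matched on gene length. In the shortest length decile of all genes, 10.8% had a peak in NSCs, 11.8% in Neurons and 10.1% in Astrocytes, and the olfactory genes with an NSC peak had a median length of 0.948 kb. Against length-matched random lists, the fixed axon guidance list, which is not the KEGG pathway, lay within the random range in all 3 peak lists, with 32 of 35 (random 27 to 34) in NSCs. The fixed glutamate receptor list, with 20 of 20 in NSCs (random 15 to 20), cannot be judged in this way. Its upper random limit was the whole list in each cell type, so no count could lie above it.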

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

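All tests in this part were chosen after the results were seen, except that of gene content on chromosome 14. The immunoprecipitated libraries stood apart from the inputs in read shares that no comparison above used. Unmapped reads made up 10.3% of the NSC, 10.2% of the Neuron and 9.59% of the Astrocyte library, against 0.259% and 0.189% of the inputs. Of uniquely mapped reads, 7.02%, 6.67% and 8.04% in NSCs, Neurons and Astrocytes were not labelled as in the same chromosome, against 0.559% and 0.655% in the inputs. Mapped reads that were not unique made up 2.24%, 3.21% and 2.46% of the 3 libraries, against 0.334% to 0.484% in the inputs.

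No biological explanation was tested for these shares, since enrichment and library kind cannot be separated. Unalignable reads of another organism alone would leave the share not labelled as in the same chromosome near that of the inputs, and it was at least 10.2 times higher. Fragments joined during library preparation would raise both the unmapped share and the share not labelled as in the same chromosome. The latter was up to 14.4 times higher than in the inputs, and joined fragments remain open because enrichment from repeats would do the same. What the label counts is not defined, so reads whose mate was unmapped or not unique may be part of that share. Reads from repeats would raise the share of reads that were not unique, which was at least 4.62 times higher, and they remain open too. Joined fragments and repeats cannot be told apart here, because read pairs and sequences were not analysed.

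Peaks found in 1 cell type alone lay at low scores in all 3 cell types. Chance calling near the score minimum would leave few such peaks in the highest decile of scores, where their share was at most 0.107%. That share restates the pattern, so it lends chance calling no support of its own. Weak 6mA sites of a single cell type would also score low, so the share does not exclude them. Different 6mA signal of the cell types remains open: in the 6 comparison lists, 2.94% to 20.1% of the peaks in the highest decile held a region of the authors' comparison of immunoprecipitated libraries, and in 5 of the 6 this share was below that over all peaks (11.2% to 22.1%). Without replicates, differences between cell types and between single libraries cannot be told apart.

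Chromosome 14 held the fewest peaks per Mb of the autosomes in NSCs, Neurons and Astrocytes, with 27.4, 30.5 and 25.2, where chromosome 5, the next lowest, had 38.5, 43.8 and 36.5. Few genes on chromosome 14 are argued against, since the density outside gene classes was also low there, at most 0.662 times the median autosome. If X had fewer copies than the autosomes, fewer copies of chromosome 14 in these cells would lower the score at a matched fold at least as far as on X. The number of X copies in these cells was not established here, so that condition is not known to hold. Over 16 settings and 3 cell types the fall was 0.345 to 0.811 times that on X. It was at most 0.456 at a fold minimum of 20 and at least 0.631 at 10, and 25 of all 48 values were under 0.5. Whether the fall was particular to chromosome 14 depended on the setting. No other autosome fell further in 27 of the 48 values, with 10 of 12 at a fold minimum of 10, 3 of 12 at 15, 3 of 12 at 20 and 11 of 12 at 30, and at most 2 did in the others. In 1 of the settings, at a fold of at least 20 its median log2 score relative to peaks of like fold in NSCs, Neurons and Astrocytes was -0.20, -0.18 and -0.18, and that of chromosome 4 was -0.20, -0.20 and -0.20. All 48 values lay below the fall on X, so that prediction was not met. Because the number of X copies is not known here, a copy number difference still cannot be told apart from a lower 6mA density. The input reads per chromosome were not analysed here.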

How the results depend on the processing

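The 50 length bins, and the stricter score in 1 list against all peaks of the others, were chosen after seeing the data; the other alternatives were fixed before. Of 82 alternative values, 17 of comparisons and 6 of Txnrd3 stayed within their counting interval or within 1.5 times their count, 53 and 6 moved further, and none of the ratios changed side of 1. The cause of a move was not tested unless stated. The ratio of Neuron to NSC peak numbers went from 1.13 to 1.15 at the stricter score and 1.096 by covered length, and that of Astrocytes to NSCs from 0.953 to 0.911 by covered length. Peaks found in both other cell types went, in NSCs, Neurons and Astrocytes, to 39.5%, 35.04% and 41.6% at 50% reciprocal overlap, 54.2%, 54.1% and 54.3% with the 58045 highest-scoring peaks of each list, 54.4%, 47.2% and 57.1% at the stricter score, and 68.7%, 62.8% and 71.8% with that score in 1 list alone. Gene body shares of NSC, Neuron and Astrocyte peaks were 34.96%, 35.5% and 35.9% at the stricter score and 34.7%, 35.4% and 35.5% of covered bases. The ratio of region numbers for Neurons over NSCs was 1.22 at a fold of at least the median and 1.32 inside peaks of the higher cell type; for Astrocytes over NSCs it was 0.770 and 0.707, and for Neurons over Astrocytes 2.10 and 2.35. The gene body share of regions higher in Neurons than in Astrocytes was 35.6% at a fold of at least the median. Of regions lower in NSCs, Neurons or Astrocytes in a first comparison, the second held 13.0%, 6.88% and 14.01% at 50% reciprocal overlap. Of pairs of gene list and peak list, 2 lay above the central 95% of random lists with gene bodies only, 8 at the stricter score, 24 without matching on length and 1 with 50 length bins; 0, 0 and 4 lay below it with gene bodies only, at the stricter score and without matching. Of pairs with comparison lists, 15 lay above and 2 below in the main analysis; 14 and 1 did with gene bodies only, 50 and 10 without matching, and 10 and 1 with 50 length bins. These counts are by mid-rank percentile. Leaving out the matching lets gene length in by construction. The X to autosome ratio at the stricter score was 0.520, 0.517 and 0.479 in NSCs, Neurons and Astrocytes. At an adjusted p of 0.001, fewer terms were called by construction: 36, 32 and 40 GO terms with 29 in all 3 cell types, and 8, 3 and 12 KEGG pathways with 3 in all. The sequence content of peaks was planned and not run, for want of a genome of the files' build. With 1 library per cell type, depth was not varied, and no replicate limits these values.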

Other observations

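Redox genes had regions in both directions against NSCs, and their counts lay within the range of random lists in both directions. Regions higher in Neurons than in NSCs lay in 6 of the 24 genes: Txnrd3, Gsr, Gclc, Gss, Glrx and Slc7a11. Regions higher in NSCs than in Neurons lay in 5: Txnrd1 and Txnrd2, the cytosolic and mitochondrial thioredoxin reductases, Txn2, Gclm and Sod2. Against Astrocytes, NSCs were higher in regions of Txnrd1, Txnrd2, Txn2, Gclm, Sod1 and Slc7a11, and Astrocytes in regions of Txnrd3, Gsr, Srxn1 and Slc7a11. Among adenine methylation enzymes, Fto had regions in all 6 comparison lists and Zc3h13 in 5 of them. These genes were looked up across lists after their values were seen.

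Regions of the comparison lists lay in exons and CpG islands more often than the peaks did. Exons held 4.02% to 4.96% of the regions of the 6 comparison lists, and 2.78% of NSC, 3.05% of Neuron and 2.89% of Astrocyte peaks. CpG islands held 0.330% to 0.559% of the regions, and 0.149%, 0.210% and 0.164% of the peaks. The share of peaks in gene bodies was 39.1% in the highest decile of NSC scores, 39.0% in Neurons and 39.7% in Astrocytes, and 33.2%, 33.8% and 34.1% in the lowest decile. The comparison of these shares was chosen after the values were seen.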
